A study of Mus musculus with 5 samples.

How the data were processed

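Gene expression was measured with Affymetrix mouse arrays on total RNA of differentiated C3H10T1/2 adipocytes, 1 array for each of 5 groups: DMSO, butein, sulfuretin, DMSO1 and resveratrol. Per the labels, cells were treated for 6 h and biotinylated cRNA was made from 500 ng of total RNA. Per the submitters' processing notes, the values were made with RMA; its version, background step and output scale are not given in the sources used here. The deposited values are intensities on a linear scale, as their range shows, from 1.4 to 9340 over the arrays, although log2 values had been assumed when the comparisons were fixed. Log2 of each deposited intensity was therefore taken and no pseudocount was added. The sorted values of DMSO, butein and sulfuretin nearly coincide, as do those of DMSO1 and resveratrol, but the sets differ, so the authors' normalization appears to have been run in 2 sets. For that reason each treatment was compared with the control of its own set, which is also the control that the labels give for resveratrol.

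Of 45037 probe sets, 34945 name 1 gene in the platform annotation, 932 name several and 9160 are unnamed there. Symbols were updated by gene ID through a RefSeq gene table of assembly GRCm38.p6, which held the ID of 34741 single-gene probe sets; no coordinates are given, as the build behind the array values is not stated. Each of 18194 genes was represented by the probe set with the highest mean log2 value over the 5 arrays. A gene was counted when its highest value reached the floor, the median of the probe sets' mean log2 values (intensity 8.39), which kept 12439 genes. Values were called exactly equal within 1e-06 on the log2 scale.

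With 1 array per group no test was possible within a comparison. Genes were called higher or lower at a log2 difference of at least 1, a 2-fold criterion. For 27 gene lists fixed before the data were examined, the median log2 difference of the counted members was placed among 10000 random lists of the same size matched on level in 20 bins, and a list was said to stand apart at or below percentile 2.5 or at or above 97.5. That percentile describes these arrays only. Correlations were taken across genes and set beside 200 simulated sets of unchanged arrays that share a control.

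Genes were named by a rule fixed in advance: for each treatment the 10 highest and 10 lowest past the criterion, leaving out clone and predicted names, up to 4 members past the criterion per list, and always Prdm4, Ucp1, Ppargc1a, Pparg, Cebpa, Fabp4, Adipoq and Hmox1. For the 3 treatments together the rule took up to 10 genes each way with the largest smallest change, and for the other comparisons the 5 highest and 5 lowest. Genes named outside the rule are said to be so.

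Alternatives were fold criteria of 1.5 and 3, no floor, a floor at percentile 75, the mean of all probe sets, joint quantile normalization, centring, loess correction with a span of 0.4, the other DMSO array or the mean of both as control, and a change larger than the difference between the DMSO arrays. A further alternative was limma at an adjusted p of 0.05 with DMSO and DMSO1 as replicates, with 1 residual degree of freedom, which assumes that the lone treated arrays vary like the DMSO arrays. Quantile normalization combined with the other control or with limma, leaving out cross-hybridising probe sets, and leaving out members shared between lists were added after the data had been seen. Probe sets without a single gene name were left out of the comparisons.

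The procedure was tested on simulated data. For butein against DMSO, on 12439 genes, with noise taken from the narrow spread between resveratrol and DMSO1, 100% of the simulated 3-fold and 4-fold changes and 56% of the 2-fold changes passed the criterion, and 0 unchanged genes did, which that small noise all but assures. With the wider spread between the DMSO arrays after joint quantile normalization, 96% of the 4-fold, 92% of the 3-fold and 52% of the 2-fold changes passed, and so did 648 unchanged genes, more than the 289 genes past 2-fold with butein, so that spread is too wide for a comparison within a set. With the whole spread between sulfuretin and DMSO as noise, 52% of the 2-fold changes and 0 unchanged genes passed, the latter again all but assured by noise of that size. For resveratrol against DMSO1, 1 of 27 unshifted lists stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.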

Results

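Transcript levels were measured in adipocytes made from C3H10T1/2, a mouse mesenchymal cell line that turns into fat cells under an adipogenic cocktail. The cells received butein, sulfuretin, resveratrol or the solvent DMSO for 6 h, and total RNA went onto 5 Affymetrix expression arrays, 1 per group. A second DMSO array, named DMSO1 here, is given in the labels as the control of resveratrol. According to the series description the profiles were set side by side to look for factors for or against adipogenesis that the compounds share. Butein is a chalcone with a catechol ring, sulfuretin is an aurone with a catechol ring in which the bridge is closed into a furanone, and resveratrol is a stilbene without a catechol. The doses are not given in the labels. No group has a replicate array, so the differences have no error estimate from replicates of their own group, and the p-values given below borrow the spread between the DMSO and DMSO1 arrays. On the deposited values limma pooled that spread over all genes into a single value, so those p-values do not reflect the spread of the gene itself. Single genes near the criterion are therefore uncertain. Each array gave intensities for 45037 probe sets, and 12439 genes had a level at or above the floor on at least 1 array and were counted.

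Butein gave the widest response. Compared with DMSO, 252 genes were at least 2-fold higher and 37 at least 2-fold lower. Hmox1 (NCBI gene 15368), the heme-degrading enzyme heme oxygenase 1, was 20.9-fold higher, with an intensity of 197 in DMSO and 4134 with butein. The transcription factor genes Maff and Atf3 were 29.4-fold and 20.6-fold higher. At the other end, the lipid droplet enzyme gene Pnpla3 (NCBI gene 116939) was 9.78-fold lower and G0s2 (NCBI gene 14373), which encodes an inhibitor of adipose triglyceride lipase, was 9.57-fold lower. Pnpla3 read 8.95 with butein, near the floor, so the size of its difference is uncertain.

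The other genes among the 10 highest with butein were Osgin1 (23.0-fold), Srxn1 (14.2-fold), Gclc (13.1-fold), Ifrd1 (12.3-fold), Prg4 (11.3-fold), Txnrd1 (9.88-fold) and Noct (9.82-fold). Among the 10 lowest were Tnfrsf11b, the gene of the decoy receptor osteoprotegerin (3.58-fold lower), the proteoglycan gene Lum (3.46-fold), Plscr2 (3.28-fold), the activin antagonist gene Fst (3.17-fold), the lipogenic gene Thrsp (3.15-fold), Fam107a (2.94-fold), Npr3 (2.88-fold) and Pde5a (2.84-fold).

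Stress gene groups were higher with butein. Of 28 counted targets of NRF2, the regulator of antioxidant genes, 13 were at least 2-fold higher and none lower, with a median log2 difference of 0.98. The list holds Hmox1, Osgin1, Srxn1, which encodes sulfiredoxin, and Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis. Of 24 immediate early and short-lived transcripts, 19 passed the criterion upward and the median was 2.08, with Btg2 8.97-fold and Ier2 7.23-fold higher. In the heat shock list 10 of 21 genes were past 2-fold, among them the chaperone genes Dnajb1 (8.19-fold), Hsph1 (6.00-fold), Dnajb4 (3.33-fold) and Bag3 (3.02-fold), and the median was 0.98. The list of ATF4 and amino acid response genes had 11 of 27 members past 2-fold and a median of 0.54, led after Atf3 by Chac1 (8.81-fold), Ppp1r15a (6.91-fold) and Ddit3 (6.60-fold). Hypoxia response genes had 7 of 23 members past 2-fold and a median of 0.51, with the glucose transporter gene Slc2a1 6.73-fold, Ero1a 5.64-fold, Bhlhe40 3.33-fold and the hexokinase gene Hk2 2.79-fold higher.

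Other lists were also shifted upward with butein, namely 5 counted aryl hydrocarbon receptor targets (median 0.91; Nqo1 3.84-fold and Tiparp 3.40-fold higher), 5 metal response genes (median 0.70; the zinc exporter gene Slc30a1 2.29-fold higher) and 20 ER chaperone and unfolded protein response genes (median 0.25, none past 2-fold). In the list of 22 NF-kB and inflammatory genes the median was 0.12 and 5 were past 2-fold, including Ptgs2 (5.47-fold), Cxcl5 (3.64-fold), Cxcl1 (3.16-fold) and Ccl2 (log2 difference 1.48). Circadian clock genes had a median of 0.08, with Bhlhe40 and Nfil3 (2.10-fold higher) past the criterion. All of these lists stood apart from random lists matched on level.

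Lipid and adipocyte genes were lower with butein, mostly by less than 2-fold. Of 24 mature adipocyte genes 23 were lower and none passed the criterion, with a median of -0.31. Adipoq, the adiponectin gene, was 1.18-fold lower and Pparg and Cebpa, which encode the regulators that drive adipogenesis, were 1.11-fold and 1.38-fold lower. Fabp4 was 1.07-fold lower on its brightest probe set, but 2 dimmer probe sets of Fabp4 were 5.28-fold and 4.28-fold lower. The fatty acid and triglyceride synthesis list had a median of -0.39, with Pnpla3 and Thrsp the 2 of 21 members past 2-fold. Cholesterol synthesis and uptake genes had a median of -0.44, with 19 of 20 members lower and none past 2-fold. In the cell cycle list 23 of 26 genes were lower (median -0.42, none past 2-fold), and 5 osteoblast and chondrocyte markers had a median of -0.43.

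Regulators of adipogenesis went both ways with butein. Of 21 pro-adipogenic regulators 13 were lower and the median was -0.14, yet the 3 members past the criterion, Egr2 (3.50-fold, from a DMSO level under the floor), Cebpb (2.99-fold) and Klf4 (2.74-fold), were higher. Of 26 anti-adipogenic regulators, Ddit3, Trib3 (3.96-fold) and Sirt1 (3.05-fold) were past 2-fold higher while the median was 0. The 17 counted thermogenic and brown or beige adipocyte genes had a median of 0. In that list Prdm4, a zinc finger regulator, was 1.73-fold higher and Ppargc1a 1.21-fold higher, and Ucp1, the uncoupling protein gene, was under the floor on all 5 arrays.

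The remaining lists did not stand apart with butein: FoxO and fasting response (median 0.10, Gadd45a 5.10-fold higher), p53 targets (-0.005, with Btg2, Plk2 at 4.80-fold and Mdm2 at 3.47-fold higher), TGF-beta and YAP responsive genes (0, Skil 2.68-fold higher), fatty acid oxidation and PPAR targets (-0.13), oxidative phosphorylation (-0.15), interferon-stimulated genes (-0.003), extracellular matrix and fibroblast markers (-0.14), skeletal muscle markers (-0.058) and macrophage and blood cell markers (0). In all, 10 of the 27 lists stood apart upward and 6 downward with butein. Chance gives 5% of lists only if members vary independently, and lists share members. Between the solvent arrays, DMSO1 minus DMSO, 4 of the 27 lists stood apart upward and 3 downward, so standing apart is not limited to treated arrays. Of the lists apart with butein, pro-adipogenic regulators stood apart the same way in only 4 of 10 alternatives and osteoblast and chondrocyte markers in 6. Both medians turned upward with joint quantile normalization and the other DMSO array as control (0.057 and 0.23). With the other DMSO array alone, on a different scale, ER chaperones (-0.13) and circadian clock genes (-0.22) turned downward. Among random lists on that scale, circadian clock genes still stood apart upward (percentile 98.4), while ER chaperones did not (94.9). With the mean of all probe sets of a gene in place of the brightest, 166 genes were higher and 23 lower. Genes past 2-fold with butein had 297 other probe sets. Of these, 121 also passed the same way, 246 had the same sign and 0 passed the opposite way. For sulfuretin 10 of 29 other probe sets passed the same way and 25 had the same sign. For resveratrol these were 3 and 6 of 7. Many calls therefore rest on the brightest probe set alone. When limma took the DMSO and DMSO1 arrays as replicates, 18 genes were called higher and 2, G0s2 and Pnpla3, lower, and none after the 5 arrays had been quantile normalized together (unadjusted p under 0.05: 295 higher and 64 lower).

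**Figure D1:**
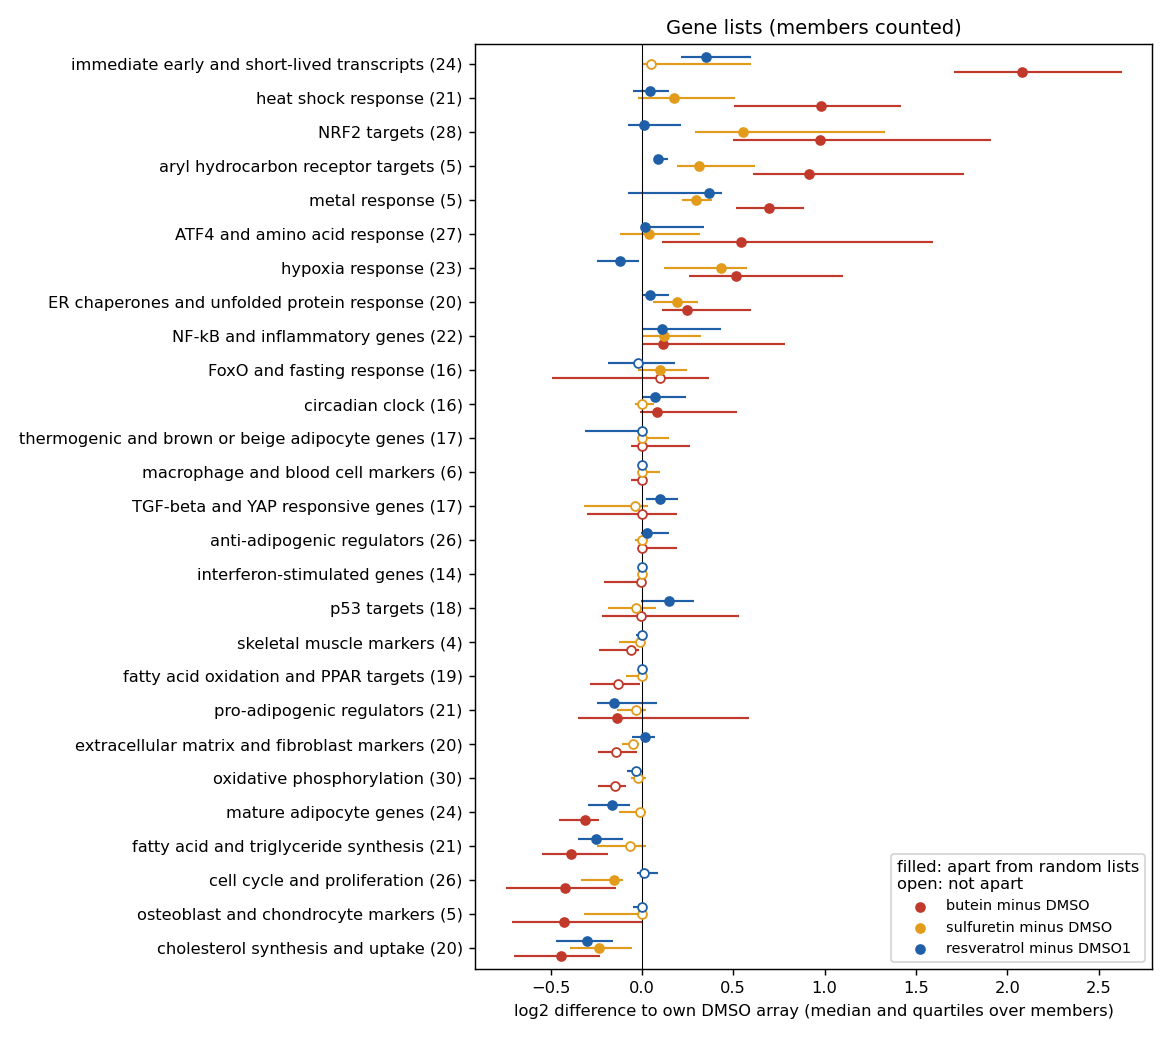
Median log2 difference between each treatment and its own DMSO array for the 27 gene lists, with lines for the quartiles over members, the number of counted members in parentheses, and filled points for lists apart from random lists. The immediate early list lies at 2.08 with butein, 0.052 with sulfuretin and 0.35 with resveratrol, while the NRF2 list lies at 0.98, 0.55 and 0.01.

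Sulfuretin gave a narrower response led by NRF2 targets. Compared with DMSO, 24 genes were at least 2-fold higher and 6 lower. Hmox1 was 13.8-fold higher, Srxn1 6.77-fold, the iron exporter gene Slc40a1 6.68-fold, the adenylate kinase gene Ak4 4.26-fold, Gclc 4.15-fold, Osgin1 3.94-fold and Gclm, the modifier subunit of the same enzyme as Gclc, 3.63-fold. Cxcl5 (3.21-fold), Slc2a1 (3.14-fold) and Txnrd1 (2.68-fold) completed the 10 highest. Lower were Pnpla3 (3.13-fold), G0s2 (2.16-fold), Thrsp (2.16-fold), Rgs2 (2.12-fold), Vgll4 (2.04-fold) and 1 gene known by a clone name.

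All 28 counted NRF2 targets were higher with sulfuretin, 9 of them by at least 2-fold, and their median was 0.55. Hypoxia response genes had a median of 0.43, with Slc2a1 and Hk2 (2.05-fold) the 2 of 23 past the criterion. Lists with smaller upward medians that stood apart were aryl hydrocarbon receptor targets (0.31, Nqo1 2.51-fold higher), metal response (0.30), ER chaperones (0.19), heat shock (0.17, none past 2-fold), NF-kB and inflammatory genes (0.12), FoxO and fasting response (0.099) and ATF4 and amino acid response (0.04, Slc3a2 2.14-fold higher). Cholesterol synthesis and uptake genes (median -0.24, 17 of 20 lower) and cell cycle genes (median -0.15, 23 of 26 lower) stood apart downward. Of 24 immediate early transcripts, Maff (2.63-fold higher) was the 1 past the criterion, and the list's median of 0.052 did not stand apart.

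Mature adipocyte genes had a median of -0.01 with sulfuretin and fatty acid and triglyceride synthesis genes -0.07, and neither list stood apart, nor did the other 13 lists. Pparg was 1.30-fold lower, Adipoq 1.03-fold lower, Fabp4 1.02-fold higher on its brightest probe set (1.12-fold and 1.37-fold lower on 2 dimmer ones) and Cebpa 1.01-fold higher. Prdm4 was 1.39-fold and Ppargc1a 1.21-fold higher, and Ucp1 was under the floor. The upward median of the ATF4 list turned to -0.004 when members shared with other lists were left out, and the list stood apart the same way in only 3 of 10 alternatives, as FoxO and fasting response did in 5. With the other DMSO array as control, on a different scale, the heat shock (-0.22), ATF4 (-0.47), ER chaperone (-0.22), aryl hydrocarbon receptor (-0.25), FoxO (-0.63) and hypoxia (-0.082) medians turned downward. On that scale 2153 genes were at least 2-fold lower, and among random lists hypoxia still stood apart upward (percentile 99.8). The others lay between percentiles 6.17 and 85.0 and did not stand apart. Here limma with the DMSO and DMSO1 arrays as replicates called 1 gene, Hmox1 (adjusted p 0.00917, for a log2 difference of 3.32 to the mean of both solvent arrays), and none after joint quantile normalization (unadjusted p under 0.05: 28 higher and 10 lower).

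Resveratrol gave the smallest differences, with 10 genes at least 2-fold higher and 8 lower than in DMSO1. Highest were the chemokine gene Cxcl10 (3.41-fold) and Depdc7 (2.51-fold), both from a DMSO1 level under the floor, Hivep3 (2.45-fold) and the matricellular gene Ccn2 (2.33-fold). The sizes and rank of Cxcl10 and Depdc7 are therefore uncertain. The group also held 4 immediate early genes, Btg2 (2.18-fold), Atf3 (2.17-fold), Jun (2.11-fold) and the nuclear receptor gene Nr4a1 (2.10-fold), together with Angptl4, the gene of a lipoprotein lipase inhibitor (2.16-fold), and Chac1 (2.01-fold). Lower were B3galt2 (log2 difference -1.32), the FGF21 co-receptor gene Klb (2.27-fold), G0s2 (2.11-fold), Pnpla3 (2.11-fold), Vsir (2.10-fold), the fatty acid receptor gene Ffar4 (2.09-fold), the succinate receptor gene Sucnr1 (2.06-fold) and 1 predicted gene. With resveratrol Ffar4 read 8.84 and Sucnr1 10.1, under that array's median probe set intensity of 11.5. Hivep3 read 9.5 in DMSO1, under that array's median of 11.1. The sizes of these differences are uncertain too. Hmox1 was 1.96-fold higher, just under the criterion. Btg2 turned to a log2 difference of -0.44 with joint quantile normalization and the other DMSO array as control, and with that array alone B3galt2 (0.79), Klb (0.066), Ffar4 (0.54) and Sucnr1 (0.45) turned upward.

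Of 24 immediate early transcripts 23 were higher with resveratrol, 4 past 2-fold, with a median of 0.35. Between the solvent arrays, DMSO1 minus DMSO on different scales, those 4 differed by 1.40 (Atf3), 0.35 (Jun), -0.22 (Nr4a1) and -0.88 (Btg2). With 1 array per group, a difference between cultures cannot be told apart from one due to resveratrol. Metal response genes (0.37), p53 targets (0.15), NF-kB and inflammatory genes (0.11), TGF-beta and YAP responsive genes (0.097) and circadian clock genes (0.069) also stood apart upward. With joint quantile normalization and the other DMSO array as control, the NF-kB (-0.16), p53 (-0.066), TGF-beta (-0.11) and circadian (-0.025) medians turned downward. Aryl hydrocarbon receptor targets (0.086), ER chaperones (0.045), heat shock (0.042), anti-adipogenic regulators (0.03), ATF4 and amino acid response (0.015), extracellular matrix and fibroblast markers (0.015) and NRF2 targets (0.01) also stood apart upward as deposited, at medians between 0.01 and 0.086. On the resveratrol and DMSO1 arrays 33.1% of the counted genes had exactly equal values, which narrows the band of the random lists. The share was 32.5% for sulfuretin and 29.9% for butein against DMSO, so the same holds for them. Extracellular matrix and fibroblast markers stood apart the same way in 3 of 10 alternatives, pro-adipogenic regulators, which were lower, in 5, and aryl hydrocarbon receptor targets and circadian clock genes in 6. The other 9 lists had medians between -0.033 and 0.011 and did not stand apart.

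Lipid gene groups were lower with resveratrol. Cholesterol synthesis and uptake genes had a median of -0.30 with 19 of 20 lower, fatty acid and triglyceride synthesis genes -0.25 with 19 of 21 lower, and mature adipocyte genes -0.16 with 23 of 24 lower. Pro-adipogenic regulators had a median of -0.15, which became 0.006 after the 5 arrays were quantile normalized together, and hypoxia response genes -0.12 with 18 of 23 lower. With the other DMSO array as control, on a different scale, mature adipocyte genes (0.098), fatty acid and triglyceride synthesis genes (0.11), pro-adipogenic regulators (0.33) and hypoxia response genes (0.30) turned upward. Among random lists on that scale they lay between percentiles 4.87 and 28.9 and did not stand apart. Pparg was 1.25-fold, Ppargc1a 1.24-fold, Cebpa 1.14-fold, Adipoq 1.10-fold and Fabp4 1.03-fold lower, the last on its brightest probe set, against 1.35-fold and 1.31-fold on 2 dimmer ones. Prdm4 was 1.17-fold higher, and Ucp1 was under the floor. The NRF2 and extracellular matrix medians turned to -0.0006 and -0.013 with the mean of all probe sets per gene, and the anti-adipogenic median to -0.013 with joint quantile normalization and the other DMSO array. No gene passed limma with the DMSO and DMSO1 arrays as replicates (unadjusted p under 0.05: 23 higher and 1 lower, or 17 and 12 after joint quantile normalization).

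**Figure D2:**
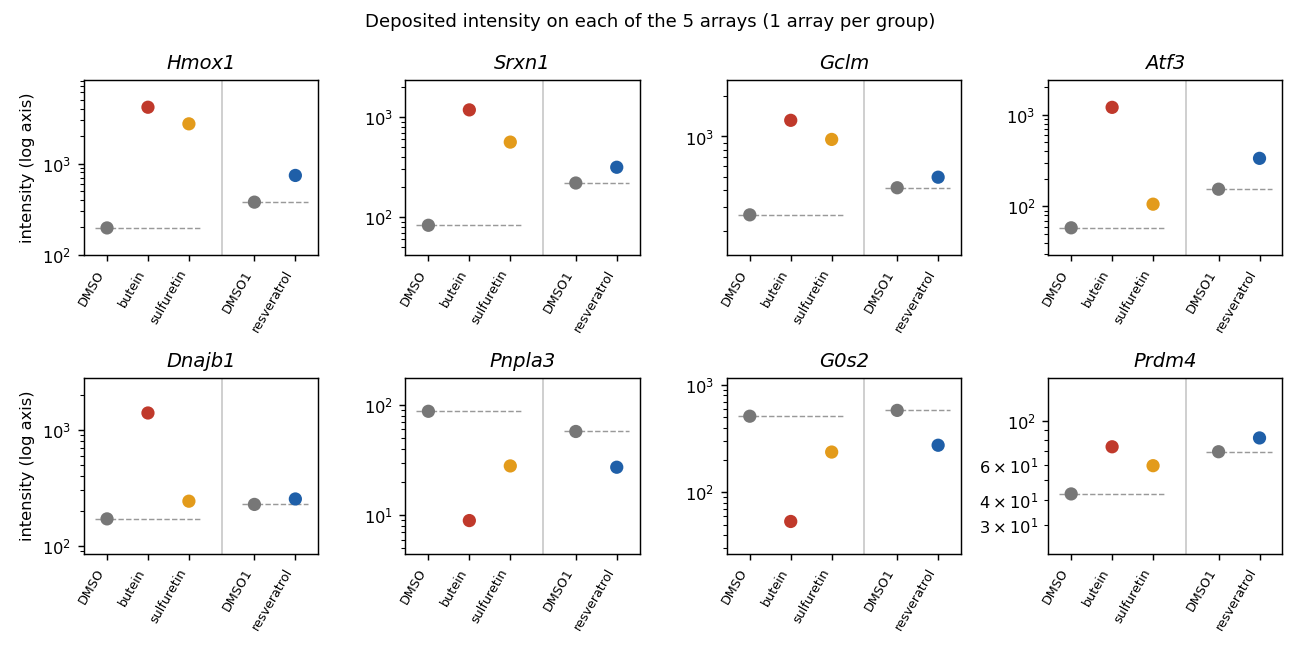
Deposited intensity, on a log axis, of 8 genes on each of the 5 arrays, with dashed lines at the DMSO level of each set. Hmox1 reads 197 in DMSO, 4134 with butein, 2721 with sulfuretin, 378 in DMSO1 and 741 with resveratrol, and levels left and right of the grey line are not on a common scale.

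Set against butein directly, sulfuretin left 129 genes at least 2-fold lower and 12 higher. The lowest were Atf3 (log2 difference -3.51), Btg2 (-3.50), Maff (-3.48), Prg4 (-3.05) and Chac1 (-3.00). The highest were G0s2 (2.15), Pnpla3 (1.64), Lpar6 (1.29), Plscr2 (1.16) and Tnfrsf11b (1.16), of which G0s2, Pnpla3, Plscr2 and Tnfrsf11b were among the genes lowest with butein. Pnpla3 and Plscr2 both read 8.95 with butein, near the floor, so the sizes of their differences are uncertain. Immediate early transcripts had a median difference of -1.84 with 19 of 24 past 2-fold, heat shock genes -0.62, ATF4 and amino acid response genes -0.52 and NRF2 targets -0.32. Fatty acid and triglyceride synthesis genes (0.33) and mature adipocyte genes (0.25) were higher with sulfuretin than with butein. With 1 array per compound no interval of these differences can be given, and limma with the DMSO and DMSO1 arrays as replicates called 3 genes, Atf3, Btg2 and Maff, all lower with sulfuretin, and none after joint quantile normalization (unadjusted p under 0.05: 9 higher and 103 lower).

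The change with resveratrol minus the change with butein had a median of -1.70 over immediate early transcripts, -1.10 over NRF2 targets, -0.92 over heat shock genes and -0.76 over hypoxia response genes. Against the change with sulfuretin, resveratrol was lower over NRF2 targets by a median of -0.61, with all 28 below 0, and over hypoxia response genes by -0.51, and it was higher over immediate early transcripts (0.26), TGF-beta and YAP responsive genes (0.26) and p53 targets (0.21). Each of these lists stood apart from random lists. The resveratrol change comes from the other set of arrays, whose scale differs (median intensity 11.1 in DMSO1 against 6.85 in DMSO). The sizes of log2 changes may therefore not be comparable between the sets. The doses are not known either, so the values are set side by side only.

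Few single genes passed the criterion in all 3 treatments. Pnpla3 and G0s2 were at least 2-fold lower in all 3 comparisons, and 0 genes were at least 2-fold higher in all 3. At a 1.5-fold criterion 9 genes were higher in all 3, namely Hmox1, Atf3, Ifrd1, Jun, Jade3, Cxcl1, Slc19a2, Fbxo30 and Klhl21. Lower at that criterion were 8 genes, Pnpla3, G0s2, Lrig1, Lfng (under the floor with butein and sulfuretin), Mc2r, Mid1ip1, Fam241a and 1 gene known by a clone name. Among the lists, cholesterol synthesis and uptake stood apart downward in all 3 treatments. There were 7 that stood apart upward in all 3, namely NRF2 targets, heat shock, metal response, ATF4 and amino acid response, ER chaperones, aryl hydrocarbon receptor targets and NF-kB and inflammatory genes, although with resveratrol the medians of 5 of them were under 0.1. Some of these calls were weak. ATF4 with sulfuretin held in only 3 of 10 alternatives and aryl hydrocarbon receptor targets with resveratrol in 6. The NRF2 median with resveratrol turned to -0.00056 with the mean of all probe sets. Butein and sulfuretin also share a control array.

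Of the 24 genes higher with sulfuretin, 23 were also past the criterion with butein, and all 6 lower genes were shared. Both compounds were compared with the same DMSO array. Unchanged arrays simulated with the whole spread between sulfuretin and DMSO as noise gave 0 genes past 2-fold in both, which noise of that size all but assures. With the spread between the DMSO arrays after joint quantile normalization, simulated arrays shared on average 109.8 higher and 110.6 lower genes. That is more than the 23 and 6 seen, but that spread was too wide for a comparison within a set. How much of the sharing comes from the shared array therefore cannot be told. An error of that array in a single gene would show with both compounds. The higher gene not shared with butein was Smyd4, named after its values were seen, at a log2 difference of 1.15 with sulfuretin and 0.54 with butein. Resveratrol shared 5 higher genes with butein (Atf3, Btg2, Chac1, Jun and Nr4a1; 0.203 for independent lists) and 4 lower genes (Pnpla3, G0s2, B3galt2 and Vsir; 0.0238). Resveratrol shared 0 higher and 2 lower genes with sulfuretin, the latter being Pnpla3 and G0s2.

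Across the 12439 genes, which are not independent replicates, the log2 differences of butein and sulfuretin had Pearson's r of 0.69 and Spearman's rho of 0.63. Unchanged arrays simulated against the shared DMSO array gave r of 0.50. The covariance was 0.0499. Error of the shared array, if independent of the responses, adds at most the variance of sulfuretin minus DMSO, 0.0372, so it does not account for all of the covariance, and with 1 control array its exact part is not known. Butein and resveratrol, which have separate controls, had r of 0.41 and rho of 0.36, and sulfuretin and resveratrol had r of 0.22 and rho of 0.19, both beside a simulated r near 0. With the other DMSO array as control these correlations became -0.71 and -0.89, and -0.71 and -0.88 when the arrays were also quantile normalized together. That swap puts the difference between the solvent arrays into the 2 comparisons with opposite signs. This drives r below 0 by construction, so the swap cannot test these correlations.

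**Figure D3:**
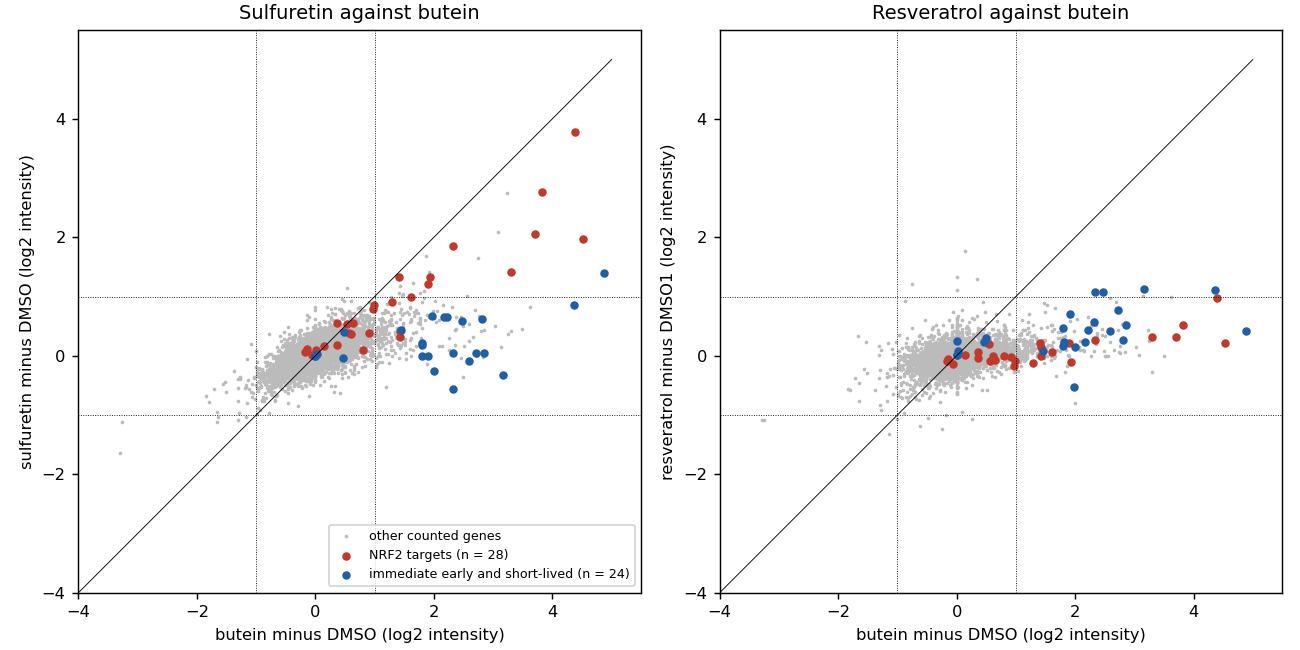
Log2 difference of each counted gene with sulfuretin (left) and resveratrol (right) against that with butein, with dotted lines at the 2-fold criterion, a solid line of equality, and the 28 NRF2 targets and 24 immediate early transcripts coloured. NRF2 targets spread along both axes on the left, while immediate early transcripts spread along the butein axis, with 19 past 2-fold with butein and 1 with sulfuretin.

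The background difference between the solvent arrays was larger than that of any treatment, with an SD of the log2 differences over counted genes of 0.54, against 0.38 for butein, 0.19 for sulfuretin and 0.14 for resveratrol. DMSO1 was at least 2-fold above DMSO for 2267 genes and below for 68, around a median shift of 0.54. The highest were the globin gene Hba-a2 (3.16), Ctse (3.08), Lgals9 (3.06), Tmem126b (3.01) and Taf15 (2.86), and the lowest Igdcc3 (-2.21), Nr4a2 (-2.19), Srrm4 (-2.06), Hes5 (-2.04) and Slc6a7 (-1.84). All of these but Lgals9 were under the floor on 1 of the solvent arrays, so their sizes and order are uncertain. The arrays of DMSO, butein and sulfuretin had a median intensity of 6.85 each, while DMSO1 and resveratrol had 11.1 and 11.5, and no probe set was exactly equal between the sets. The share of genes past 2-fold that were higher in DMSO1 was 97.1% as deposited, 62.3% after centring on the median, 45.0% after loess correction and 36.0% after joint quantile normalization. With the other DMSO array as control, on the scale of the other set, 2448 genes were lower with butein, 2153 lower with sulfuretin and 2337 higher with resveratrol. Levels were therefore compared within a set, except in limma and in the alternatives with another control.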

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

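Probe sets without a single gene name were outside the comparisons, and some of the 3688 at or above the floor passed the 2-fold criterion. With butein 35 were higher and 35 lower, with sulfuretin 5 higher and 4 lower, and with resveratrol 1 higher and 2 lower, each against the DMSO array of its set. The most different ones were picked after their values were seen. In 1 case the same probe set was higher by 3.04 on the log2 scale with butein and by 2.87 with sulfuretin. Another differed by -2.34 with butein and by -1.17 with resveratrol. Their genes are unnamed here, and no explanation was tested.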

How the results depend on the processing

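The arrays carry no replicates, so leaving out an array was not possible, and the only spread available for limma is that between the DMSO arrays. No paired analysis was possible because each group has 1 array. Combinations of 2 choices, leaving out cross-hybridising probe sets, which moved none of its counts past the tolerance, and lists without shared members were chosen after seeing the data. Over all alternatives 970 values of named genes and 675 list medians kept their call, or the lack of one, and 105 counts and 16 correlations did not move past the tolerance. Of the rest, 82 values of named genes and 51 list medians lost a call, 49 and 43 gained one, 6 and 35 turned direction, and 75 counts and 8 correlations moved. List calls kept on the same side in the fewest of 10 alternatives were ATF4 with sulfuretin and extracellular matrix with resveratrol (3 each), pro-adipogenic regulators with butein (4) and resveratrol (5), FoxO with sulfuretin (5), and osteoblast markers with butein, aryl hydrocarbon receptor targets and circadian clock with resveratrol (6 each). The cause was not tested unless given. With the floor at percentile 75, 6 list medians had too few members and have no value.

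The fold criterion moves the counts by construction. At 1.5-fold, higher and lower genes numbered 623 and 307 for butein, 169 and 47 for sulfuretin, 42 and 45 for resveratrol, 122 and 352 for sulfuretin minus butein, 5706 and 210 for DMSO1 minus DMSO, and 9 and 8 for all 3 treatments. At 3-fold they numbered 107 and 8 for butein, 9 and 1 for sulfuretin, 1 and 0 for resveratrol, 2 and 52 for sulfuretin minus butein, 420 and 14 for DMSO1 minus DMSO, and 0 lower in all 3.

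With the mean of all probe sets, butein had 166 higher and 23 lower genes and DMSO1 minus DMSO 27 lower, and with resveratrol the NRF2 median turned to -0.00056 and the extracellular matrix median to -0.013. With a floor at percentile 75, resveratrol had 5 lower genes and DMSO1 minus DMSO 1011 higher and 12 lower, as fewer genes were counted; with no floor DMSO1 minus DMSO had 189 lower. Changes larger than the difference between the DMSO arrays left 4 lower genes with resveratrol. For DMSO1 minus DMSO, joint quantile normalization gave 279 higher and 495 lower genes, centring 499 and 302, and loess correction 305 and 373. Joint quantile normalization also gave 1 gene higher in all 3 treatments and a median of 0.0063 for pro-adipogenic regulators with resveratrol. Without shared members, the ATF4 median with sulfuretin was -0.0036.

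With limma and the DMSO arrays as replicates, 18 genes were higher and 2 lower with butein, 1 and 0 with sulfuretin, 0 and 0 with resveratrol, 0 and 3 for sulfuretin minus butein, and 0 were lower in all 3 treatments. At an unadjusted p under 0.05 these were 101 and 80, 8 and 28, 23 and 1, and 2 and 59. After joint quantile normalization limma called 0 higher and 0 lower with each of butein, sulfuretin and resveratrol and for sulfuretin minus butein. There is 1 residual degree of freedom, and the spread it estimates is that between the DMSO and DMSO1 arrays. As deposited, the prior degrees of freedom were infinite, so every gene was tested against a single pooled spread. After joint quantile normalization they were 4.14. Each contrast with solvent was taken to the mean of both DMSO arrays. These lie on different scales as deposited, so those counts also hold the difference between the sets.

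The other DMSO array as control sets arrays of different scales against each other. It gave 2448 lower genes for butein, 80 higher and 2153 lower for sulfuretin, 2337 and 74 for resveratrol, and 2 higher and 1 lower in all 3. Correlations became 0.894 for butein and sulfuretin, -0.71 for butein and resveratrol and -0.89 for sulfuretin and resveratrol. The difference between the solvent arrays enters butein and sulfuretin with the same sign and resveratrol with the opposite sign, which drives these values. With resveratrol, B3galt2 turned to 0.79, Klb to 0.066, Ffar4 to 0.54 and Sucnr1 to 0.45, and 7 lists stood apart. List medians that turned with resveratrol were mature adipocyte 0.098, pro-adipogenic 0.33, fatty acid synthesis 0.11, hypoxia 0.30 and extracellular matrix -0.029. With sulfuretin they were heat shock -0.22, ATF4 -0.47, ER chaperones -0.22, aryl hydrocarbon receptor -0.25, FoxO -0.63 and hypoxia -0.0817, and with butein ER chaperones -0.13 and circadian clock -0.22. Hypoxia with sulfuretin and circadian clock with butein still stood apart upward among random lists, at percentiles 99.8 and 98.4.

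With the mean of the DMSO arrays as control, counts were 160 higher and 292 lower for butein, 11 and 150 for sulfuretin, 162 higher for resveratrol, and 2 higher and 1 lower in all 3. The correlations with resveratrol became -0.30 for butein and -0.62 for sulfuretin, again with the difference between the solvent arrays entering with opposite signs. Medians turned to 0.11 for pro-adipogenic regulators, 0.10 for hypoxia and -0.029 for extracellular matrix with resveratrol, to -0.11 for heat shock, -0.18 for ATF4, -0.044 for ER chaperones and -0.20 for FoxO with sulfuretin, and to -0.059 for circadian clock with butein. Circadian clock with butein still stood apart upward among random lists (percentile 98.9).

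With joint quantile normalization and the other DMSO array together, counts were 777 higher and 385 lower for butein, 517 and 289 for sulfuretin and 300 and 529 for resveratrol, where 207 of the 289 butein genes, 18 of 30 sulfuretin genes and 5 of 18 resveratrol genes stayed past 2-fold. The correlations were 0.894 for butein and sulfuretin, -0.71 for butein and resveratrol and -0.88 for sulfuretin and resveratrol. With resveratrol Btg2 turned to -0.44 and Ffar4 to 0.054, and 8 lists stood apart. Medians with resveratrol turned to -0.013 for anti-adipogenic regulators, -0.16 for NF-kB, -0.066 for p53, -0.025 for circadian clock, -0.13 for extracellular matrix and -0.11 for TGF-beta. With sulfuretin ATF4 turned to -0.019 and FoxO to -0.025, and with butein pro-adipogenic regulators turned to 0.057 and osteoblast markers to 0.23.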

Other observations

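The lists in this paragraph were chosen after values had been seen, some of them because a member stood out, so they describe the arrays and are not independent evidence. Of 31 proteasome subunit genes 25 were higher with butein, at a median log2 difference of 0.15 and none past 2-fold, while the medians with sulfuretin and resveratrol were 0. Glycolysis and glucose transport genes had medians of 0.17 with butein, 0.31 with sulfuretin and -0.13 with resveratrol over 16 genes. MAP kinase phosphatase and Sprouty genes, which encode brakes on growth factor signalling, had a median of 1.46 with butein, 8 of 15 being at least 2-fold higher, against 0.13 with sulfuretin and 0.086 with resveratrol. The GADD45, BTG and TRIB families had medians of 1.99, 0.042 and 0.25. Small leucine-rich proteoglycans and secreted matrix regulators, picked partly from the lowest genes with butein, had medians of -0.90, -0.47 and -0.16, and 7 of 16 were at least 2-fold lower with butein.

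Receptors for metabolites and hormones of adipocytes had medians of -0.33 with butein, 0 with sulfuretin and -0.48 with resveratrol over 15 genes. Some of them had prompted the list. Without those first noticed, 8 genes remained, whose medians were -0.25, 0 and -0.27, and 7 of the 8 were lower with resveratrol. These 8 had been part of the full list when its median was read, so the smaller list is not a fresh test.

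Tests chosen after the result was seen were the joint normalization and the bands of level for the solvent arrays with the simulated difference, the difference of slopes for butein and sulfuretin with its simulation and the size of the trend, and the dimmer adipocyte probe sets for Fabp4; the other tests below were set out before their result was seen. DMSO1 lay above DMSO for 97.1% of the genes past 2-fold. One factor for the whole array is argued against, since the median difference ranged over 0.42 log2 between 4 bands of level, from 0.73 in the lowest to 0.31 in the highest. The share after centring on the median, 62.3%, decides nothing, as a simulated difference in 60% of the genes also went from 95.8% to 38.1% on centring. Whether separate normalization of the sets caused the split cannot be told apart from a culture or array difference. Joint quantile normalization took the share to 36.0%, but it took the simulated difference to 46.8%, so that test does not separate them. Both stay open, as each set has its own solvent array and no biological explanation was tested.

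Butein and sulfuretin differed by gene group. The slope of the sulfuretin difference on the butein difference was 0.622 over NRF2 targets and 0.126 over immediate early transcripts, and the slopes differed by 0.497 (95% bootstrap interval over members 0.355 to 0.654, which is no error between arrays). The lists were fixed beforehand but this pair was picked after its values were seen, and its gap is the largest of 351 pairs when scaled by the size of the butein differences. In 1000 simulated sets with a single slope of 0.355 for every gene, the largest scaled gap of any pair was 1.32, against 3.83 observed. This argues against one smaller size for every gene on these arrays, unless the shared DMSO array was off for a whole list. An error of that kind would enter both differences of the list alike, and with 1 such array it cannot be told apart. Noise of dim probe sets is not settled. On at least 1 array 25 of 28 and 20 of 24 members reached percentile 75 of level, and the slope difference among these was 0.504. A member can reach that level through the butein array alone, so this filter cannot decide. Maff, for example, read 17.8 in DMSO and 525 with butein. The difference was 0.494 after loess correction, but that correction moved little; an intensity trend is argued against by its size, at most 0.084 over members with butein and 0.027 with sulfuretin, beside a median absolute change of 1.70 with butein. The hypothesis that the compounds act on different pathways may hold for these arrays, but a response that is not proportional to dose stays open because doses are not in the labels, and there is 1 array per compound.

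Probe sets of Fabp4 disagreed with butein, with log2 differences of -0.10 and -0.17 on the brighter pair, at DMSO intensities of 9134 and 4159, and of -2.40 and -2.10 on the dimmer pair, at 422 and 232. Saturation of the bright probe sets could hide a change, and this cannot be told apart, because only 3 of 76 probe sets as bright as the next-brightest one (3.95%) differed by 0.5 log2 or more. That dim probe sets of abundant adipocyte genes read short-lived RNA in general is argued against, as 19 dimmer probe sets of other mature adipocyte genes differed from the brightest by a median of 0.018. What the dim Fabp4 probe sets read remains open, since their sequences were not used here.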
